A study of Mus musculus with 24 samples.

How the data were processed

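RNA was taken from the retinal pigment epithelium (RPE), the pigmented cell layer that lies against the photoreceptors and takes up their shed outer segments, of wild-type 129S1/SvlmJ mice carrying the Leu450 form of Rpe65. Per the labels, the animals were kept under 12 h of light and 12 h of dark on a standard diet, and light came on at 7 am. Libraries were made from total RNA with a kit that does not mark strand, per the labels' protocols. The deposited table holds raw counts of reads per gene for 24 libraries, with 1 column per mouse and Ensembl gene identifiers. The submitters' processing notes name STAR, HTSeq and the mouse build mm10. Their roles, versions and settings, the annotation release and any filter were not given in the sources used here. The authors' count columns are whole numbers with different totals, so they were treated as counts that had not been normalized. The labels give the 3 libraries of each time as separate mice, and a chi-square comparison of all 276 pairs of libraries found none that differed by less than sampling noise (lowest value per degree of freedom 5.85).

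Because the reads carry no strand, reads of a gene and of an antisense or overlapping partner cannot be told apart. Overlap was checked for 327 genes, those taken by the naming rule given below, which include only some members of each list. All 327 were found by identifier in GENCODE vM21 (GRCm38, the build named mm10), and 105 of them share exonic bases with another annotated gene. The remaining list members were not checked for overlap. The share was 18% of exonic bases for Dbp (with Sphk2), 17.3% for Sqstm1 (with Mrnip), 34.4% for Ctsd (with a predicted gene on the same strand), 15.7% for Fam184b, 15.1% for Pilra and 12.6% for Tub. Their values are less certain for that reason. Coordinates are from that annotation, counted from 1.

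Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 on the time groups, which left 18065 of 54532 genes and 99.92% of the counts. Library sizes were scaled by TMM (trimmed mean of M-values). Dispersions were estimated with estimateDisp, a quasi-likelihood model with robust priors (glmQLFit) was fitted, and glmQLFTest gave the p-values. These were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as a call. All adjusted p-values come from this edgeR test unless another tool is named. The first comparison was an F test over the 7 differences from 0 h in a model with a mean per time. The second was an F test of the cosine and sine terms of a 24 h period, from which the fitted peak-to-trough log2 ratio and the fitted peak hour were taken. Standard errors of these came from a jackknife over the 24 libraries. Samples cover 1 day without its last 8 h and with none between 9 h and 15 h, so the test is of a daily shape and not of its recurrence. The remaining comparisons set each later time against 0 h, 3 mice against 3, and set the mean of 15 h and 16 h (night, 6 libraries) against the mean of 1, 3, 5, 6 and 9 h (day, 15 libraries). The 7 comparisons with 0 h share the same 3 libraries, so their results are not independent of each other. Log2 fold changes are given with standard errors (SE), and levels as CPM, counts scaled to a common library size, with TMM scaling, as mean ± SD over mice.

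Lists of genes were fixed by name. They held core clock genes, autophagy machinery, selective autophagy receptors, lysosomal hydrolases, lysosomal membrane proteins, the V-ATPase, MiT/TFE factors and mTORC1, outer segment phagocytosis, RPE identity and visual cycle, melanin and pigment granules, cholesterol synthesis, fatty acid oxidation and ketogenesis, immediate early genes, heat shock, the unfolded protein response, glucocorticoid targets, oxidative phosphorylation, cytosolic ribosomal proteins, interferon response and mitochondria-encoded transcripts. Markers of rods, cones, inner retina, choroid endothelium, fibroblasts with mural cells, macrophages with mast cells, melanocytes with Schwann cells, red blood cells, skeletal muscle and lens with ciliary body, and sex-linked genes, made up the rest of the 31 lists. Members whose symbols were not found among the genes tested included Ccpg1, Cnga3, Hbb-b1, Hbb-b2 and Tnnc2. Called members were counted per list and set against all other genes by Fisher's exact test, two-sided, adjusted over the lists. Counts were also made with p-values adjusted over the list alone. For the 8 contrasts each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members move one way on balance and compares them with no other genes. Marker levels were summarised as the median log2 CPM of the members and compared between times by permutation tests with 100000 resamples.

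The named genes follow a rule. Core clock members, Optn, Tfeb, Tfe3, Mitf, Sqstm1, Map1lc3b, Lamp1, Ctsd, Mertk, Rpe65, Cirbp and Rbm3 were taken whatever their values. Some items that the rule or the lists take are not reported here. For the 24 h component the 10 called genes outside the clock list with the largest peak-to-trough ratio and a mean of at least 5 CPM were added. For 1 h against 0 h and for night against day, the rule took up to 10 higher and 10 lower genes with the largest fold change, and for each other time up to 4 and 4, among calls with at least 1 CPM and no overlap between the groups. Predicted gene models and Y-linked genes were passed over. Up to 4 members with the smallest adjusted p were taken from each list described. The groups, comparisons, tests, lists, this rule and the first set of other settings listed next were fixed before the data were examined.

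The other settings fixed in advance were DESeq2 1.42.0 with its own size factors, limma-voom, RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in 12 libraries, a replicate block, the rod marker level as a covariate, fits of the 2 groups alone, fits without 0 h or without 15 h and 16 h, 2 other definitions of day, and leaving out each library in turn. Another 3 alternatives were chosen after seeing the data. They left out mouse 3 of 6 h and mouse 3 of 15 h, did so with the rod marker covariate, or weighted each library by limma-voom. Other assignments of libraries to times were drawn 100 times, and all 10 splits were made for pairs of groups.

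Depth ranged from 14073440 to 17492470 counts per library. The common biological coefficient of variation, the spread between mice beyond counting error, was 25.6% over 24 libraries and 15.3% over the 22 left without mouse 3 of 6 h and mouse 3 of 15 h. The procedure was tested on simulated data made from the real means, library sizes and edgeR dispersions, with 18065 genes and 100 genes changed at each of 2 fold sizes. Counts were drawn independently for each gene, with no library standing apart and no factor shared between genes. The rates below therefore need not hold for the real data. In simulated data for 9 h against 0 h, 55% of 2-fold and 77% of 4-fold changes were recovered, and 8.33% of calls were false. For night against day the shares were 77%, 97% and 5.43%, and for the 24 h component 50%, 85% and 4.26%. DESeq2 gave 18.9%, 16% and 20.3% false calls in the same order, and limma-voom 6.43%, 6.04% and 5.71%.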

Results

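Gene expression in mouse RPE was measured by RNA-seq at 8 times over a light and dark cycle, to ask how autophagy and lysosomal genes vary through the day. RNA was collected 0, 1, 3, 5, 6, 9, 15 and 16 h after light onset from 3 mice at each time, 24 mice in all. Times of 1 to 9 h lay in the light phase and 15 h and 16 h in the dark phase. Libraries held 14073440 to 17492470 counts, and 18065 genes were tested.

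Mouse 3 of 15 h and mouse 3 of 6 h stood apart from the other 22 libraries. On the first principal component, which held 38.2% of the variance, they lay at 199.9 and 49.3, and the others between -25.1 and -3.5. Cytosolic ribosomal protein genes made up 3.99% of counts in mouse 3 of 15 h and 1.8% in mouse 3 of 6 h, against 0.877% to 1.26% in the others. Mitochondria-encoded transcripts made up 0.837% and 3.34% of counts, against 3.84% to 6.81%. Globin transcripts made up 0.639% and 0.321%, against 0.0405% to 0.197%. Deviations of genes from the mean of the other libraries fell with gene length in these libraries (Spearman rho across genes, which are not independent replicates, -0.32 and -0.41, against -0.20 to 0.19 elsewhere). Each count of genes is therefore also given for the 22 other libraries, an alternative added after seeing the data.

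**Figure D1:**
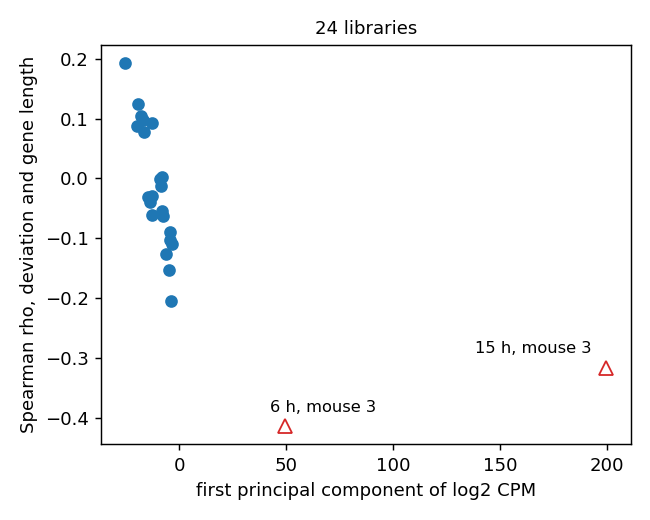
Position of each of the 24 libraries on the first principal component (x axis) against the Spearman rho across genes between a gene's deviation and its length (y axis). Mouse 3 of 15 h and mouse 3 of 6 h lie at 199.9 and 49.3 on the component with rho of -0.32 and -0.41, and the other libraries lie between -25.1 and -3.5.

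Core clock genes followed a daily pattern. Arntl (Bmal1; ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), an activator of the clock loop, fell from 28.5 ± 3.39 CPM at 0 h to 6.85 ± 1.43 at 9 h and stood at 19.4 ± 1.78 at 16 h (SD, n = 3). Its fitted 24 h component had a log2 peak-to-trough ratio of 2.22 ± 0.17 (jackknife SE) with a peak at 21.2 ± 0.1 h after light onset (adjusted p = 1.18e-08). Npas2, a partner of Arntl, had a ratio of 2.03 ± 0.18 and a peak at 22.7 ± 0.4 h (adjusted p = 8.7e-05). Ciart, Nr1d1 and Dbp, which this activator drives, peaked in the light phase. Ciart (ENSMUSG00000038550, chromosome 3, 95878503 to 95882251), a repressor of the loop, had the largest ratio of the list, 3.63 ± 0.29, and peaked at 7.0 ± 0.3 h (adjusted p = 1.18e-08). Nr1d1 (Rev-erb alpha; ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), which represses Arntl, reached 193 ± 12.6 CPM at 3 h and 46.7 ± 10.2 at 15 h, with a ratio of 1.93 ± 0.18 and a peak at 5.0 ± 0.4 h (adjusted p = 1.66e-07). Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a PAR bZIP output factor, went from 164 ± 51.6 CPM at 0 h to 390 ± 45.8 at 9 h and peaked at 7.5 ± 0.4 h with a ratio of 1.63 ± 0.18 (adjusted p = 3.28e-06). Cry1 (ENSMUSG00000020038, chromosome 10, 85131700 to 85185064), a late repressor, peaked in the early dark phase at 15.3 ± 0.4 h, with a ratio of 0.92 ± 0.08 (adjusted p = 1.4e-07). No library was taken between 9 h and 15 h or after 16 h, so fitted peaks in these spans, here and below, lie in unsampled parts of the day. Such peaks rest on the cosine shape, which their SE does not cover. Npas2, for example, was at 5.27 CPM at 16 h and 10.1 at 0 h and at 3 h.

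Of the 24 core clock genes, 13 had a 24 h component and 11 varied over time, and 18 and 16 did when adjusted over the list alone. Without the pair of libraries that stood apart 15 and 18 were called. Both shares exceeded those of all other genes (Fisher's exact test, adjusted p = 4.16e-16 and 1.23e-14). Other called members included Per2 (1.51 ± 0.25, peak 9.6 ± 0.6 h), Nfil3 (1.43 ± 0.25, 19.4 ± 0.4 h), Tef (0.89 ± 0.09, 10.3 ± 0.7 h), Nr1d2 (0.83 ± 0.10, 8.2 ± 0.7 h), Cry2 (0.55 ± 0.09, 8.4 ± 0.3 h) and Hlf (0.46 ± 0.08, 10.7 ± 0.8 h). Per1 varied over time (adjusted p = 5.99e-06), but its 24 h component of 1.20 ± 0.50 did not pass (adjusted p = 0.215). Adjusted over all genes, Per3 (1.08 ± 0.13, adjusted p = 0.055) and Clock (0.79 ± 0.16, adjusted p = 0.0933) did not pass in 24 libraries. Both passed without the 2 libraries that stood apart (1.07e-07 and 0.000309), and both are among the 18 that passed when adjusted over the list alone. Log2 ratios of Rora, Rorb, Bhlhe40, Bhlhe41, Csnk1d, Csnk1e and Fbxl21 were 0.10, 0.34, 0.14, 0.34, 0.21, 0.14 and 0.50, with adjusted p of 0.218 or more. The call of Per2 (adjusted p = 0.0181) ended without mouse 2 of 0 h, mouse 3 of 0 h or mouse 3 of 9 h (up to 0.0557) or without the time 0 h (0.308). That of Hlf (0.0487) held in 10 of 37 alternatives, whose adjusted p ran from 5.64e-05 to 0.413. Those of Cry1 and Nr1d1 ended without 15 h and 16 h (0.104 and 0.112) and that of Nr1d2 without 0 h (0.0958).

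**Figure D2:**
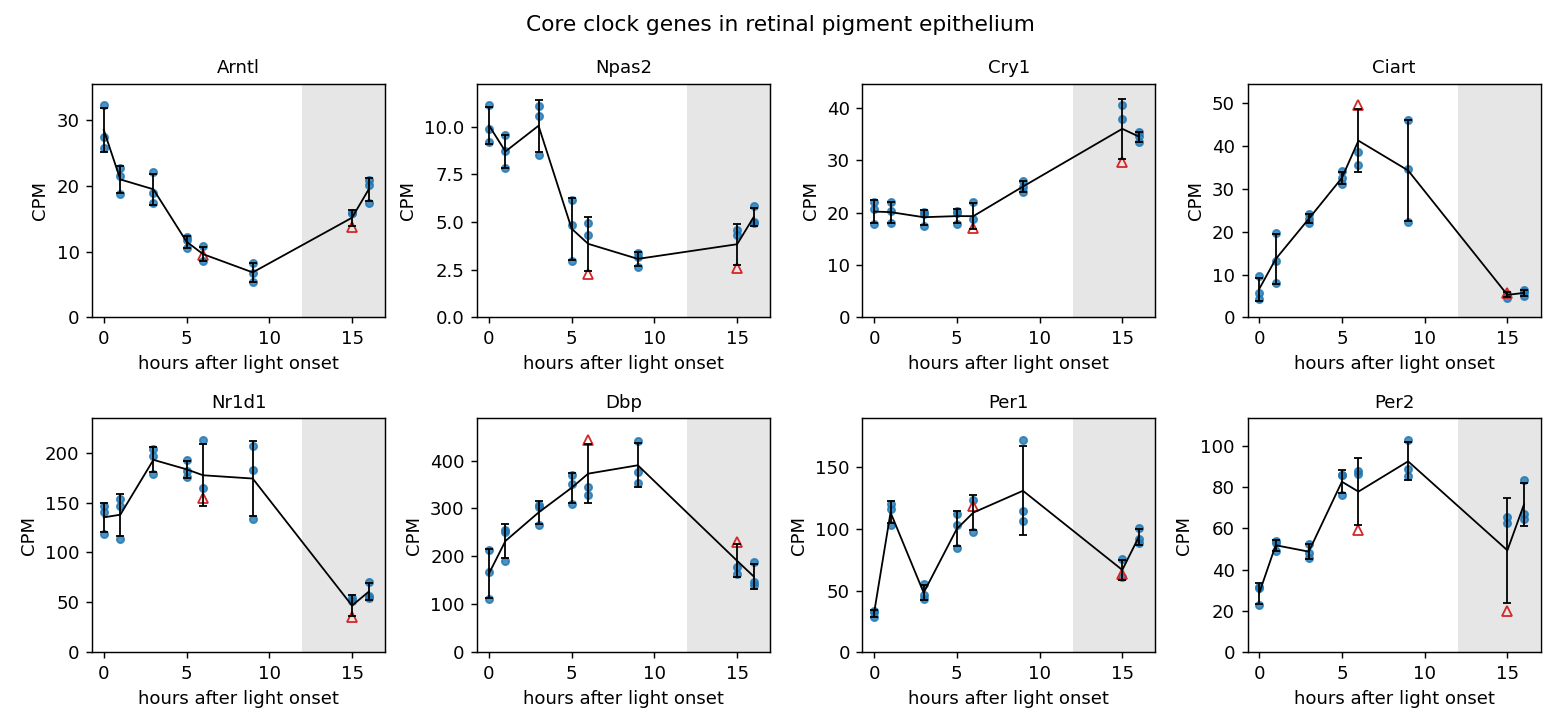
CPM (y axis) against hours after light onset (x axis) for Arntl, Npas2, Cry1, Ciart, Nr1d1, Dbp, Per1 and Per2, with points for mice, open red triangles for mouse 3 of 6 h and mouse 3 of 15 h, lines and bars for mean ± SD (n = 3) and grey for the dark phase. Arntl falls from 28.5 at 0 h to 6.85 at 9 h, while Dbp goes from 164 to 390.

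Over all genes, 195 varied over time and 302 had a 24 h component. Over the 22 libraries the counts were 2882 and 1149, with 195 and 299 genes shared with the sets from 24 libraries. Outside the clock list, and among called genes with a mean of at least 5 CPM, the largest 24 h component was that of Impg1. Impg1 (ENSMUSG00000032343, chromosome 9, 80313330 to 80465481), a proteoglycan of the matrix around photoreceptors, had a log2 ratio of 2.91 ± 0.62 and peaked at 23.3 h (adjusted p = 0.00975). Nr2e3, a rod transcription factor, had 2.60 ± 0.55 (0.0127), and Pde6a, a subunit of the rod phosphodiesterase, had 2.39 ± 0.61 (0.0178). Cyp26a1 (ENSMUSG00000024987, chromosome 19, 37697808 to 37701528), which breaks down retinoic acid, peaked in the morning at 3.9 h with 2.52 ± 0.34 (0.000768). Aldh3a1 (ENSMUSG00000019102, chromosome 11, 61207537 to 61218421), an aldehyde dehydrogenase, peaked at 17.6 h with 1.85 ± 0.36 (0.0011). Etv4 (ENSMUSG00000017724, chromosome 11, 101769742 to 101785371), an ETS factor downstream of FGF signalling, peaked at 9.6 h with 2.05 ± 0.29 (0.000283). The remaining genes were Esrrb (2.35 ± 0.67), Ptprn (2.26 ± 0.43), Pitpnm3 (2.06 ± 0.37) and Casz1 (1.94 ± 0.46), with adjusted p of 0.0479, 0.0208, 0.00247 and 0.0234. With the rod marker level as a covariate the call of Impg1 ended at a ratio of 1.17 (adjusted p = 0.208, in a range up to 0.423 over all alternatives), and that of Pitpnm3 stood at 0.0511. Pde6a and Nr2e3 are among the rod markers that make up this level, so the covariate is no test of them. Without 0 h, calls of Impg1 (0.362), Nr2e3 (0.189), Pde6a (0.399), Pitpnm3 (0.307) and Casz1 (0.523) ended. Cyp26a1, Aldh3a1, Impg1, Nr2e3 and Pde6a lost their calls without 15 h and 16 h (0.742, 0.132, 0.0796, 0.164 and 0.163).

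Among single libraries, leaving out mouse 1 of 0 h ended the call of Pde6a (adjusted p = 0.0737) and that of Casz1 (0.0968), and the call of Casz1 also ended without mouse 2 of 0 h (0.0748), mouse 3 of 0 h (0.0651) or mouse 3 of 9 h (0.0642). Ptprn lost its call without the same 4 libraries, and its adjusted p ran from 0.000548 to 0.45 over the alternatives. Esrrb kept its call in 15 of 37 alternatives (0.00273 to 0.6). The count of 302 became 806 without mouse 3 of 15 h. The count of 195 became 123 without mouse 2 of 0 h, 125 without mouse 1 of 3 h, 127 without mouse 3 of 3 h, 128 without mouse 1 of 9 h and 127 without mouse 1 of 16 h. It became 315 without mouse 3 of 6 h, and 864, 987 and 1226 without mouse 1, mouse 2 and mouse 3 of 15 h.

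Lysosomal and autophagy genes, the subject of the series, showed little variation past the test. Optn (optineurin, a selective autophagy receptor; ENSMUSG00000026672, chromosome 2, 5020642 to 5064051) stood at 113 ± 9.08 CPM at 0 h, with a highest mean of 115 ± 3.19 at 3 h and a lowest of 97.1 ± 7.17 at 9 h (SD, n = 3), and its 24 h component of 0.15 ± 0.08 did not pass (adjusted p = 0.489). Tfeb (ENSMUSG00000023990, chromosome 17, 47737030 to 47792419), a transcription factor of lysosome biogenesis, had a component of 0.53 ± 0.25 (0.223), and its mean of 55.8 ± 25.7 CPM at 15 h took in the mouse that stood apart. Components of Tfe3, Mitf, Sqstm1, Map1lc3b, Lamp1 and Ctsd were 0.05, 0.18 ± 0.10, 0.09 ± 0.08, 0.10 ± 0.06, 0.14 ± 0.11 and 0.79 ± 0.44, with adjusted p between 0.252 and 0.917. Ctsd, an aspartic protease of lysosomes, was at 2670 ± 219 CPM at 0 h, 3310 ± 143 at 9 h and 3000 ± 90.8 at 16 h, and its mean at 15 h was 6870 ± 6590, from 2946 and 3182 in mouse 1 and mouse 2 and 14482 in mouse 3, which stood apart.

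Of 161 lysosomal and autophagy genes tested, 1 varied over time and 0 had a 24 h component, and 0 and 0 did when adjusted over the list alone. The 1 gene was Ostm1, a subunit of the lysosomal chloride exchanger (largest log2 difference from 0 h 0.43, adjusted p = 0.0447). Its call held in 12 of 35 alternatives (3.46e-06 to 0.181) and ended on leaving out any 1 library of 0, 1, 3, 5, 9 or 16 h or mouse 1 or 2 of 6 h. At an unadjusted p under 0.05, edgeR's test gave 21 genes over time and 27 for the 24 h component. Over time DESeq2 called 12 and limma-voom 1, and for the 24 h component 4 and 0. Against the share among all other genes neither count passed (Fisher's exact test, p = 1 and 0.119). Components nearest to the threshold were those of Acp5, a tartrate-resistant phosphatase (1.00 ± 0.22, peak 9.6 h, adjusted p = 0.0543), Ostm1 (0.45 ± 0.12, 11.2 h, 0.0575), Tpcn2, a lysosomal cation channel (0.53 ± 0.15, 7.1 h, 0.073), and Ctss, a cysteine protease (0.67 ± 0.21, 8.5 h, 0.0787). Macrophage and mast cell markers had their highest median level at 9 h and their lowest at 16 h. From which cells the RNA of these lysosomal genes came was not tested.

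In the 22 libraries, 21 lysosomal and autophagy genes varied over time and 13 had a 24 h component, and 16 and 13 did when adjusted over the list alone. Neither share passed a test against all other genes (Fisher's exact test, p = 0.386 and 0.332). Genes varying over time in this fit included Ostm1 (adjusted p = 0.000153), Mfsd8 (0.00101), Acp5 (0.00131), Ctsh (0.00287), the autophagosome protein Wipi1 (0.007) and the receptor Sqstm1 (0.0422). Genes with a 24 h component included Acp5 (0.000914) and Tmem192 (0.00791). By part of the pathway, and over 24 libraries, genes varying over time numbered 0 of 44 for autophagy machinery, 0 of 19 for selective receptors, 0 of 52 for hydrolases, 1 of 29 for membrane proteins (2 adjusted over the list alone) and 0 of 17 for the V-ATPase. When adjusted over the list alone, 2 lysosomal membrane genes had a 24 h component, and 0 in each of the other 4 parts. Leaving out mouse 3 of 15 h gave 8 genes with a 24 h component, leaving out mouse 2 of 6 h gave 2, and leaving out mouse 1 of 1, 6, 9 or 15 h or mouse 2 of 16 h gave 1. Genes varying over time numbered 4, 5 and 4 without mouse 1, 2 and 3 of 15 h, and 2 without mouse 3 of 6 h.

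**Figure D3:**
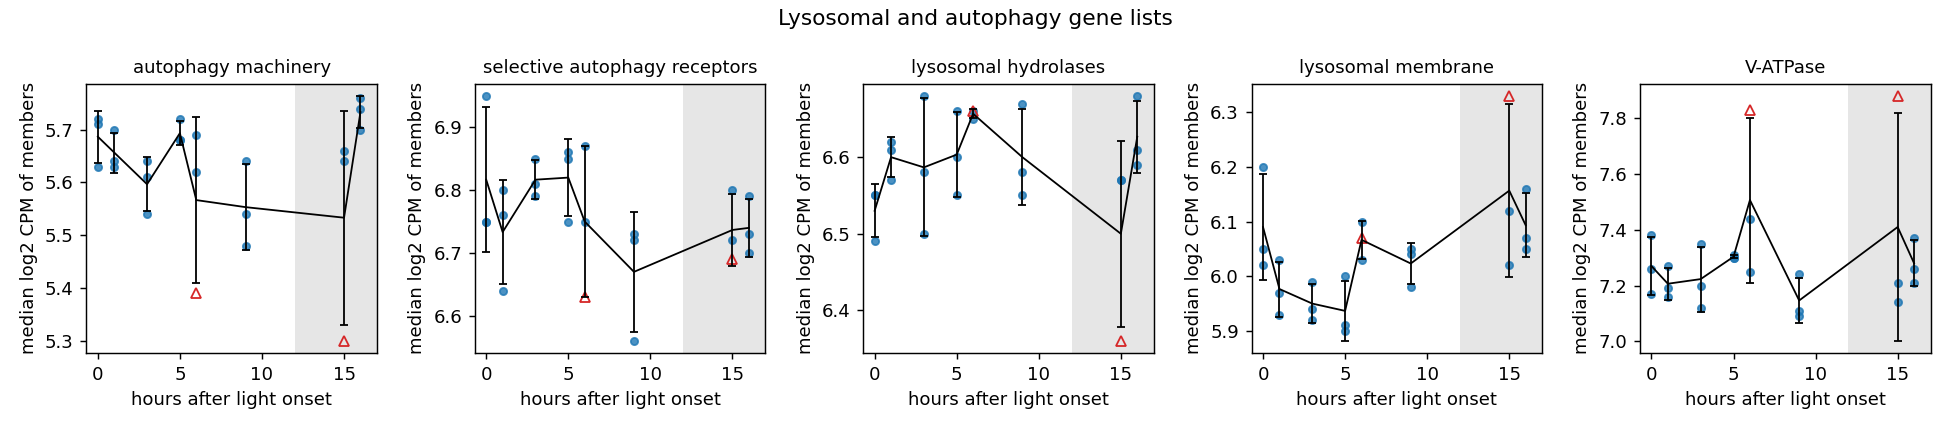
Median log2 CPM of the members (y axis) against hours after light onset (x axis) for autophagy machinery, selective receptors, hydrolases, lysosomal membrane and V-ATPase lists, with points for mice, open red triangles for mouse 3 of 6 h and mouse 3 of 15 h, and lines and bars for mean ± SD (n = 3). No member passed the test for a 24 h component in 24 libraries.

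Regulators and neighbours of these pathways gave single calls. Adjusted over the list alone, 1 of 33 MiT/TFE and mTORC1 genes varied over time and 2 had a 24 h component. Mtor, the kinase itself, varied over time (largest difference from 0 h 0.61, adjusted p = 0.0325), and Rragd, a GTPase that recruits it to lysosomes, had a 24 h component of 0.54 ± 0.08 with a peak at 22.1 h (0.0208). Among 25 outer segment phagocytosis genes, Tub varied over time (0.0367) and had a component of 1.31 ± 0.26 with a peak at 23.7 h (0.00843), while the uptake receptor Mertk had 0.37 ± 0.19 (0.515). In the 22 libraries Mertk varied over time (0.000501), but its component of 0.395 did not pass (0.0585). Of 26 RPE identity and visual cycle genes, Bmp4 (1.08, adjusted p = 0.00373) and Lrat, which esterifies retinol (0.74, 0.0405), varied over time, with 8 called when adjusted over the list alone. Rpe65, the retinoid isomerase, stood at 4320 ± 428 CPM at 0 h and 5710 ± 514 at 16 h, and its component of 0.56 ± 0.31 did not pass (0.138). At 15 h Rpe65 was at 11808 CPM in mouse 3, against 4576 and 4633 in mouse 1 and mouse 2. In the 22 libraries it varied over time (0.000504), and its component was 0.27 (0.208). Glucocorticoid targets held 4 of 12 genes that varied over time (9 adjusted over the list alone), a larger share than among all other genes (Fisher's exact test, adjusted p = 9.74e-05). They were Fkbp5 (1.61, 0.00269), Tsc22d3 (1.52, 0.00718), Sgk1 (0.72, 0.0228) and Cdkn1a (1.12, 0.0422). Components of the cold-inducible Cirbp and Rbm3 were 0.30 ± 0.16 (0.572) and 0.45 ± 0.07 (0.232), and Rbm3 passed in the 22 libraries (0.000224).

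Several of these calls rested on few libraries. Mtor was called over time in 16 of 35 alternatives (adjusted p from 8.87e-06 to 0.113), Tub in 18 (1.85e-05 to 0.407), Lrat in 16 (6.34e-06 to 0.0963), Cdkn1a in 17 (8.61e-06 to 0.157) and Sgk1 in 26 (5.29e-08 to 0.0646). The 24 h calls of Rragd and Tub held in 30 and 34 of 37, with the highest values, 0.283 and 0.373, without 0 h and with the rod covariate in the 22 libraries.

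Each later time was then set against 0 h, always with the same 3 libraries of 0 h. At 1 h after light onset 2 genes rose and 0 fell. Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960), a clock gene that also responds directly to light and hormone signals, went from 31.6 ± 2.63 to 113 ± 8.95 CPM (SD, n = 3; log2 fold change 1.84, SE 0.17, adjusted p = 1.23e-05). Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784), a feedback inhibitor of cytokine signalling through STAT5, went from 8.84 ± 2.81 to 29 ± 1.47 CPM (1.72, SE 0.23, 0.00293). By 3 h, Cish was at 8.96 ± 1.03 and Per1 at 48.3 ± 6.04. The 12 glucocorticoid targets had a median log2 change of 0.54 at 1 h, with 10 positive and 0 called (5 adjusted over the list alone), among them Tsc22d3 at 0.95 (0.692) and Cdkn1a at 0.84 (0.52). As a set they rose relative to other genes (camera adjusted p = 1.28e-08, adjusted p = 0.0448 with an estimated correlation). Both single calls held in every alternative, and the count was 66 in the 22 libraries (36 higher, 30 lower, 2 shared) and 19 without mouse 3 of 15 h.

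At 3 h against 0 h, 0 genes were called by edgeR, with 551 at an unadjusted p under 0.05. DESeq2 called 5 and limma-voom 0. The largest changes among clock genes were 1.79 for Ciart (adjusted p = 0.12) and 0.83 for Dbp (0.813), and 9 clock genes passed when adjusted over the list alone, 7 higher and 2 lower. In the 22 libraries 55 genes were called, 15 higher and 40 lower. Leaving out mouse 3 of 15 h gave 4, and leaving out mouse 3 of 0 h, mouse 1 of 1 h or mouse 2 of 1 h gave 1.

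At 5 h, 14 genes rose and 6 fell against 0 h. The largest rises were those of the clock repressor Ciart (log2 fold change 2.29, SE 0.30, adjusted p = 0.00109), Etv4 (1.80, SE 0.23, 0.00109), Per1 (1.66, SE 0.17, 6.5e-05) and Per2 (1.53, SE 0.28, 0.0336). The largest falls were those of Fam184b (-1.68, SE 0.22, 0.00123), the Wnt agonist Rspo2 (-1.41, SE 0.22, 0.00524), Arntl (-1.31, SE 0.16, 0.00051) and Rasl11b (-1.18, SE 0.17, 0.00348). Rspo2 went from 17.8 ± 2.61 to 6.69 ± 0.908 CPM and Etv4 from 2.96 ± 0.356 to 10.4 ± 1.72 CPM (SD, n = 3). Bmp4, a secreted growth factor, rose by 1.05 (0.00715). The interferon response list had 20 of 20 members positive, with a median of 0.65, 0 called and 10 called when adjusted over the list alone. Its lead members were Irf9 (0.54, adjusted p = 0.0541), Oasl2 (1.20, 0.109), Usp18 (1.32, 0.155) and Ifih1 (0.64, 0.191). As a set these genes rose relative to other genes (camera adjusted p = 1.68e-18, adjusted p = 0.0448 with an estimated correlation), and 13 were called in the 22 libraries. The count was 548 in the 22 libraries (302 higher, 246 lower, 20 shared). It was 194 without mouse 3 of 15 h, 35 without mouse 3 of 6 h, and 8 without mouse 1 of 0 h or mouse 1 of 5 h. It was 11 or 12 without mouse 2 or 3 of 0 h, mouse 2 or 3 of 5 h, mouse 1 of 1 h, mouse 1 of 3 h, mouse 2 of 6 h or mouse 3 of 9 h. Per2 kept its call in 23 of 36 alternatives (1.48e-08 to 0.19), and Rspo2 lost it without mouse 3 of 0 h, mouse 1 of 5 h or mouse 3 of 5 h (up to 0.0827). Bmp4 lost its call at 5 h without mouse 1 or 3 of 0 h or mouse 1 of 5 h (up to 0.101).

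At 6 h, 20 genes rose and 10 fell. Ciart reached 41.3 ± 7.38 CPM from 6.62 ± 2.71 (adjusted p = 0.000149) and Nog, an inhibitor of BMP signalling, 389 ± 44.8 from 140 ± 15.7 (log2 fold change 1.48, SE 0.16, 0.000112). Etv4 and Per1 rose by 1.89 and 1.84 (SE 0.23 and 0.17, 0.000293 and 1.24e-05). Fam184b went from 5.76 ± 1.01 to 1.48 ± 0.141 CPM (-1.96, SE 0.23, 0.00015), Arntl changed by -1.57 (SE 0.16, 3.21e-05), Npas2 by -1.38 (SE 0.28, 0.044) and the adenylate cyclase Adcy1 by -1.11 (SE 0.22, 0.0421). Among list members, Bmp4 rose by 0.99 (0.0155) and the kinase Sgk1 by 0.72 (0.0421). Lysosomal hydrolases rose as a set by camera, with 39 of 52 positive and a median of 0.15 (adjusted p = 0.000592, but adjusted p = 0.368 with an estimated correlation), and 0 members were called. Mouse 3 of the 6 h group stood apart, and in it the hydrolases deviated by a median of 0.29 and the V-ATPase genes by 0.35. Npas2, Adcy1 and Sgk1 kept their calls in 14, 14 and 12 of 36 alternatives (highest adjusted p 0.246, 0.219 and 0.246), Etv4 and Fam184b lost theirs in a fit of the 2 groups alone (0.0842 and 0.0961), and Bmp4 lost its call without any mouse of 0 h or mouse 2 of 6 h (up to 0.137). The count was 423 in the 22 libraries (246 higher, 177 lower, 30 shared). It was 588 without mouse 3 of 15 h, 8, 8 and 9 without mouse 1, 2 and 3 of 0 h, and 9 and 15 without mouse 2 and 3 of 6 h. It was 17 to 19 without mouse 1 or 2 of 1 h, mouse 2 or 3 of 3 h, mouse 2 or 3 of 5 h, mouse 2 or 3 of 9 h, or mouse 1 or 2 of 16 h.

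At 9 h, 44 genes rose and 91 fell. Per1 reached 131 ± 36.1 CPM (log2 fold change 2.05, SE 0.17, adjusted p = 1.07e-06), Ciart rose by 2.37 (SE 0.30, 0.000462) and Etv4 by 1.92 (SE 0.23, 0.000331). The largest falls were those of Impg1 (19.9 ± 7.43 to 2.03 ± 0.741 CPM, 0.0299), Lrtm1 (4.07 ± 0.759 to 0.462 ± 0.0434, 0.0323), Fabp12 (4.31 ± 1.67 to 0.502 ± 0.267, 0.037) and the rod axoneme gene Rp1 (70.4 ± 28 to 8.35 ± 6.73, 0.0462). Rod markers were lowest at this time, with a median log2 change of -2.40 and 3 of 20 called (18 adjusted over the list alone), among them Pde6a (-2.75, 0.0383). Cone markers Opn1mw (-2.72, 0.0163) and Gnb3 (-2.20, 0.0309) also fell. The chaperones Hspa4 and Hsp90aa1 fell by 0.35 and 0.57 (0.0447 and 0.046), and kept their calls in 10 and 12 of 36 alternatives (highest adjusted p 0.376 and 0.339). With the rod marker level as a covariate 6 genes were called, 3 higher and 3 lower, and the calls of Impg1, Lrtm1, Fabp12 and Ciart ended (adjusted p = 0.383, 0.339, 0.357 and 0.0618). The rod level did not overlap between 0 h (6.51 or more) and 9 h (5.32 or less), and the median SE of all genes went from 0.268 to 0.347 with it. Changes of Impg1 and Fabp12 shrank from -3.29 and -3.085 to -1.24 and -1.08 (SE 0.67 and 0.52), while Lrtm1 stood at -2.22 (SE 0.85) and Ciart at 1.99 (SE 0.39). It is no test of Rp1 and Pde6a, which are part of that level. The lowest adjusted p of Impg1 over all alternatives was 6.02e-05 and that of Rp1 0.000401.

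In the 22 libraries 1497 genes were called at 9 h (631 higher, 866 lower, 135 shared). The 135 calls became 582 without mouse 3 of 15 h. They became 25, 28 and 62 without mouse 1, 2 and 3 of 0 h, and 27, 44 and 34 without mouse 1, 2 and 3 of 9 h. They became 70 to 89 without mouse 1, 2 or 3 of 1 h, mouse 1, 2 or 3 of 3 h, mouse 1 of 5 h, mouse 2 of 6 h or mouse 1 of 16 h. Impg1, Lrtm1 and Fabp12 lost their calls without any 1 mouse of 0 h or of 9 h (up to 0.168, 0.143 and 0.175), Impg1 also without a low-count filter (0.086) and Fabp12 without mouse 1 of 16 h (0.0555). Pde6a kept its call in 22 of 36 alternatives (0.000196 to 0.5), Opn1mw in 29 of 35 (0.000114 to 0.33) and Gnb3 in 29 of 36 (0.000238 to 0.499). Rp1 kept its call in 14 of 36 alternatives (0.000401 to 0.88).

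At 15 h, 3 h into the dark, 35 genes rose and 39 fell against 0 h, with 1 of the 3 libraries standing apart. Cys1, a protein of primary cilia, went from 8.43 ± 1.62 to 37.1 ± 15.8 CPM (log2 fold change 2.13, SE 0.30, adjusted p = 0.00462). Wnt5b went from 5.08 ± 0.59 to 15 ± 6.65 (1.56, SE 0.28, 0.0135), and Lingo4 from 1.23 ± 0.191 to 5.09 ± 4.03 (2.03, SE 0.41, 0.0361). The glucocorticoid target Tsc22d3 went from 43.9 ± 5.4 to 126 ± 28 (1.52, SE 0.25, 0.0113). Falls were largest for Impg1 (-3.29, SE 0.68, 0.0398), Pde6a (119 ± 38.9 to 16.3 ± 8.67 CPM, 0.0429), the myeloid receptor Adgre4 (5.51 ± 3.7 to 0.841 ± 0.309 CPM, 0.0113) and the B cell factor Pax5 (2.89 ± 0.243 to 0.45 ± 0.361 CPM, 0.0476). In the 22 libraries 259 genes were called, 143 higher and 116 lower, of which 60 were shared with the 74. The call of Lingo4 ended there as its change shrank to 1.15 (SE 0.32, 0.0737), so its size rested on mouse 3 of 15 h. Calls of Impg1 (-3.08, SE 0.84, 0.0898) and Pde6a (-2.86, SE 0.60 over 24 libraries and -2.87, SE 0.78 over 22, 0.0889) ended there with a wider SE at a similar change. With the rod marker level as a covariate in 24 libraries, the change of Impg1 shrank to -1.71 (SE 0.61) and its call ended (0.0536). All 8 named calls ended in a fit of the 2 groups alone (0.73). The lowest adjusted p over the alternatives lay between 6.7e-09 for Cys1 and 0.00106 for Lingo4.

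The 15 h count moved with most libraries. It was 3296 and 3423 without mouse 1 and mouse 2 of 15 h, 169 without mouse 3 of 6 h, and 9, 2 and 33 without mouse 1, 2 and 3 of 0 h. Values of 34 to 48 came without mouse 2 or 3 of 1 h, mouse 2 or 3 of 3 h, mouse 1 or 3 of 5 h, mouse 2 of 6 h, mouse 1 or 3 of 9 h, or mouse 1 of 16 h. Without mouse 2 of 0 h the call of Cys1 ended (adjusted p = 0.065), that of Wnt5b without any 1 mouse of 0 h (up to 0.0871), that of Tsc22d3 without mouse 1 or 2 of 0 h and that of Adgre4 without mouse 2 or 3 of 0 h (up to 0.065) or with limma-voom (0.0717). Pax5 kept its call in 15 of 35 alternatives, Lingo4 in 22 of 36, Impg1 in 18 and Pde6a in 19.

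At 16 h, 11 genes rose and 10 fell. Per1 was at 93.5 ± 6.24 CPM (log2 fold change 1.57, SE 0.17, adjusted p = 0.000167), Cish at 22.2 ± 1.97 (1.33, SE 0.23, 0.016), Tsc22d3 at 106 ± 7.97 (0.0452) and Nog at 319 ± 30.1 (1.19, SE 0.16, 0.00158). Cry1 rose by 0.77 (0.016) and Nr1d1 changed by -1.16 (0.0075). The largest falls were those of the myeloid receptor Pilra, from 2.07 ± 0.922 to 0.205 ± 0.0532 CPM (0.0319), and the B cell adaptor Bank1, from 2.28 ± 1.13 to 0.353 ± 0.0685 (0.0391). H2-Ob fell from 4.16 ± 1.07 to 0.862 ± 0.403 (0.028) and Ms4a4b from 3.16 ± 0.306 to 0.783 ± 0.167 (-2.01, SE 0.26, 0.00158). Cx3cr1, a receptor of microglia and macrophages, changed by -1.91 (0.00158), and macrophage and mast cell markers were at their lowest median level at this time. Glucocorticoid targets rose as a set (median 0.44, 10 of 12 positive, camera adjusted p = 4e-07, adjusted p = 0.0448 with an estimated correlation). The count was 405 in the 22 libraries (242 higher, 163 lower, 21 shared), and 148 and 34 without mouse 3 and mouse 1 of 15 h. It was 13, 10 and 8 without mouse 1, 2 and 3 of 0 h, and 7, 11 and 7 without mouse 1, 2 and 3 of 16 h. Tsc22d3 kept its call in 18 of 36 alternatives (1.77e-06 to 0.214), Bank1 in 21 (0.00112 to 0.217), Pilra in 28 (0.000537 to 0.212), and Cish and H2-Ob in 30 each (8.16e-06 to 0.106 and 0.000107 to 0.213). Nr1d1 lost its call without mouse 3 of 0 h, mouse 2 of 16 h or mouse 3 of 16 h (up to 0.0765), and Cry1 without mouse 2 or 3 of 0 h or any 1 mouse of 16 h (up to 0.147) or with the rod covariate (0.169).

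**Figure D4:**
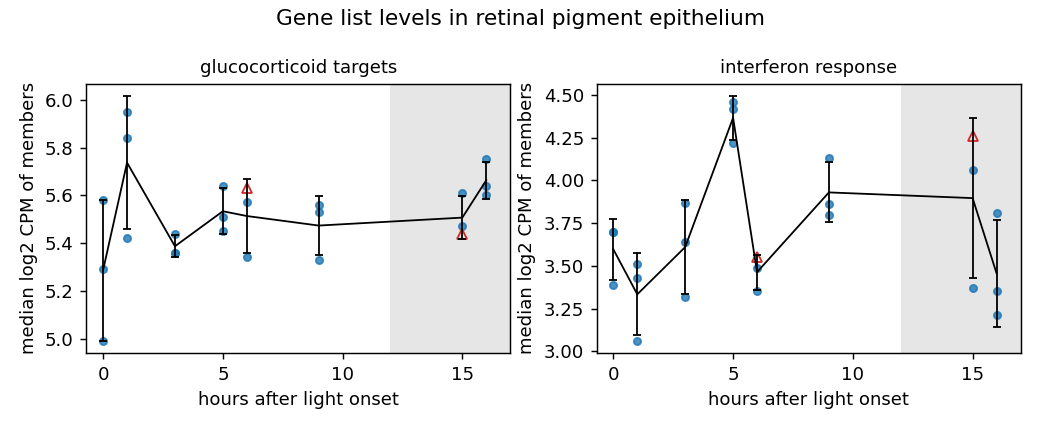
Median log2 CPM of the 12 glucocorticoid targets and the 20 interferon response genes (y axis) against hours after light onset (x axis), with points for mice, open red triangles for mouse 3 of 6 h and mouse 3 of 15 h, and lines and bars for mean ± SD (n = 3). Against 0 h the median changes were 0.54 at 1 h and 0.44 at 16 h for glucocorticoid targets and 0.65 at 5 h for interferon response genes.

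Night against day compared 6 libraries of 15 h and 16 h with 15 libraries of 1 to 9 h and called 159 genes higher at night and 92 lower. Clock genes again separated by phase. Cry1 was at 35.3 ± 3.74 CPM at night and 20.6 ± 2.75 by day (log2 fold change 0.785, SE 0.075, adjusted p = 5.23e-06) and Nfil3 at 14.7 ± 1.07 and 8.46 ± 2.53 (0.00325). Nr1d1 was at 53.6 ± 11.3 and 173 ± 28.5 (-1.69, SE 0.12, 8.21e-08) and Ciart at 5.51 ± 0.618 and 29 ± 11.5 (1.37e-06). Outside the clock, genes higher at night were Aldh3a1 (77.6 ± 32.5 and 27.9 ± 8.87 CPM, 0.000172), Lingo4 (4.29 ± 2.7 and 1.32 ± 0.504, 0.000198), and Rasl11a (12.4 ± 1.42 and 5.86 ± 1.9, 1.89e-05). Also higher were the ubiquitin ligase Rnf144b (29.3 ± 2.3 and 16.8 ± 3, 4.36e-05), Palm3 (17.8 ± 9.32 and 8.56 ± 0.983, 0.0018), Klhdc8a (187 ± 53.4 and 108 ± 14.7, 0.000198) and Tprkb (289 ± 53.6 and 169 ± 20.3, 4.7e-06). For Lingo4, Aldh3a1, Palm3, Klhdc8a and Tprkb the highest night value was that of mouse 3 of 15 h, which stood apart. Their log2 changes of 1.73, 1.46, 1.04, 0.785 and 0.778 became 1.33, 1.28, 0.70, 0.61 and 0.655 in the 22 libraries. All 5 stayed called there (adjusted p of 0.00212 or less). Genes lower at night included Cyp26a1 (2.29 ± 0.983 and 11.7 ± 4.46 CPM, 0.000131) and Fabp7, a lipid carrier (0.154 ± 0.135 and 1.36 ± 0.443, 0.000397). Also lower were the TGF-beta family member Gdf10 (16.4 ± 4.9 and 40.9 ± 8.49, 0.000412), the collagen crosslinking enzyme Lox (12.8 ± 4.48 and 24.3 ± 4.41, 0.00507) and Rasd2 (-1.32, SE 0.16, 0.000155). Grin3a, Cdc25b and the cyclic nucleotide phosphodiesterase Pde8b changed by -1.01, -0.75 and -0.64 (0.0118, 0.0182 and 0.0253). In the 22 libraries these became -0.858, -0.569 and -0.511, and the change of Lox went from -0.903 to -0.735. Changes of Cry1, Rasd2 and Nfil3 grew there, to 0.825, -1.396 and 0.88, the last from 0.83.

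Among list members at night, the glucocorticoid targets Fkbp5 and Tsc22d3 rose by 0.83 and 0.68 (adjusted p = 0.00264 and 0.0154) and Angptl4 changed by -0.98 (0.0163), and the chaperones Hspa1b and Stip1 rose by 0.56 and 0.27 (0.0397 and 0.0341). Of the 251 calls, 45 had no overlap between the groups. In the 22 libraries 843 genes were called, 520 higher and 323 lower, with 242 shared. The count was 1124, 1288 and 460 without mouse 1, 2 and 3 of 15 h, and 122, 148 and 141 without mouse 1, 2 and 3 of 16 h. Without mouse 1 of 16 h the calls of Grin3a (0.0504) and Pde8b (0.0701) ended, without mouse 2 that of Pde8b (0.0557), and without mouse 3 those of Cdc25b (0.0795) and Pde8b (0.0932). Stip1 and Hspa1b kept their calls in 21 and 20 of 37 alternatives (highest 0.18 and 0.125).

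For the contrasts with 0 h, groups of 3 mice did not overlap for any gene called. These were 2, 20, 30, 135, 74 and 21 genes at 1, 5, 6, 9, 15 and 16 h. Chance gives such an arrangement for 10% of genes taken without selection. The calls were picked for a difference between these same libraries, so their lack of overlap says nothing about chance.

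Set tests over the 31 lists, the union of lysosomal and autophagy genes and the 8 contrasts made 76 calls out of 256 with camera at the preset correlation. Permuted time labels gave a median of 60 such calls and up to 80, and 6 of 100 assignments, the real one included, gave as many. Calls that held with an estimated correlation in 24 libraries were those of glucocorticoid targets at 1 h and 16 h and of interferon response genes at 5 h. Over the 22 libraries they also held for core clock genes at 5, 6, 9 and 16 h (adjusted p = 0.0339, 0.0159, 0.0481 and 0.044 with an estimated correlation). Lysosomal hydrolases had medians of 0.08, 0.15, 0.11 and 0.13 at 5, 6, 9 and 15 h (camera adjusted p = 0.00744, 0.000592, 0.00576 and 0.0361). Their adjusted p = 0.566, 0.368, 0.558 and 0.639 with an estimated correlation. V-ATPase genes had 0.23 at 6 h with 13 of 17 positive (0.0062, and adjusted p = 0.419 with an estimated correlation), and 0.0889 without mouse 3 of 6 h. Autophagy machinery had 0.05 at 16 h with 34 of 44 positive (0.0292, and adjusted p = 0.368 with an estimated correlation). Lysosomal membrane genes had 0.08 at 5 h with 18 of 29 positive (0.00798, and adjusted p = 0.368 with an estimated correlation). The union had 0.05, 0.11 and 0.04 at 5, 6 and 16 h (0.0177, 0.000959 and 0.0227, and adjusted p = 0.368, 0.233 and 0.368 with an estimated correlation). Of the union and its 5 parts, fry called the union at 6 h (adjusted p = 0.0273, 0.0709 in the 22 libraries). Over the 22 libraries fry called membrane genes at 5 h, hydrolases at 9 h, autophagy machinery and selective receptors at 16 h and autophagy machinery at night (0.0317, 0.024, 0.00856, 0.027 and 0.0071). Hydrolases at 5 h lost the call without mouse 1 of 0 h (0.0546) or mouse 1 of 5 h (0.0505), and autophagy machinery at 16 h without mouse 2 of 0 h (0.0608), mouse 3 of 0 h (0.0973) or mouse 3 of 16 h (0.0993).

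For the remaining lists, genes with a 24 h component over 24 libraries were as follows. Fatty acid oxidation and ketogenesis held 2 of 23 (5 adjusted over the list alone), Angptl4 (1.11 ± 0.24, peak 2.9 h) and Cpt1a, the gate of mitochondrial fatty acid import (0.69 ± 0.10, peak 22.6 h). Fibroblast and mural cell markers held 2 of 15 (4 adjusted over the list alone), Col3a1 (0.66 ± 0.17) and Col1a1 (0.63 ± 0.17), with peaks at 2.2 h and 2.0 h. Heat shock held 1 of 18, Hspa1b (0.85 ± 0.20, peak 18.7 h), and melanocyte and Schwann cell markers 1 of 10, Kit (0.85 ± 0.14, peak 22.1 h). Rod markers held 2 of 20 (9 adjusted over the list alone), Pde6a and Nr2e3, and cone markers 1 of 11, Gnb3 (1.79 ± 0.39). Glucocorticoid targets held 2 of 12 (8 adjusted over the list alone), Angptl4 and Tsc22d3. RPE identity genes held 0 of 26 (4 adjusted over the list alone), and melanin and pigment granule genes 0 of 14 and macrophage and mast cell markers 0 of 21 (1 each adjusted over the list alone). Tsc22d3, Hspa1b and Kit kept these calls in 14, 26 and 28 of 37 alternatives (highest adjusted p 0.518, 0.263 and 0.406), and Cpt1a, Col3a1, Col1a1 and Gnb3 in 33, 33, 29 and 29 (highest 0.219, 0.124, 0.272 and 0.438).

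The count was 0 by either adjustment for cholesterol synthesis (22 genes), immediate early genes (23), the unfolded protein response (18), oxidative phosphorylation (36), cytosolic ribosomal proteins (45), interferon response (20), mitochondria-encoded transcripts (13), inner retina (21), endothelium (14), red blood cell (6), skeletal muscle (9), lens and ciliary body (12) and sex-linked genes (5). In the test over time, 37 of 45 ribosomal protein genes and 4 of 36 oxidative phosphorylation genes passed when adjusted over the list alone, and these lists deviated by 2.32 and 1.94 in mouse 3 of 15 h.

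Markers of other cells were present in all groups. Rod markers had a median level of 6.25 ± 0.40 log2 CPM at 0 h and 3.85 ± 0.83 at 9 h (SD, n = 3). The difference between times did not pass a permutation test adjusted over the 12 marker lists (adjusted p = 0.281, unadjusted 0.0936). Endothelial markers ranged from 5 ± 0.26 at 16 h to 5.86 ± 0.37 at 9 h (adjusted permutation p = 0.281), macrophage and mast cell markers from 4.92 ± 0.13 at 16 h to 5.62 ± 0.17 at 9 h (0.624), and fibroblast and mural cell markers from 6.7 ± 0.19 at 16 h to 7.01 ± 0.01 at 3 h (0.263). All other marker lists had adjusted permutation p of 0.263 or more. In the 22 libraries the endothelial, macrophage and fibroblast lists each had 0.0633 (unadjusted 0.0158, 0.0138 and 0.0147). Macrophage and mast cell markers were higher at 9 h and lower at 16 h than at 0 h by camera (adjusted p = 0.00708 and 0.00365, and 0.723 for both with an estimated correlation). The mean rod marker level was higher at 0 h than at each other time, so each comparison with 0 h also compared different amounts of rod RNA. Mitochondria-encoded transcripts were highest at 0 h too (11.2 ± 0.5 log2 CPM). By camera they were lower at each later time but 9 h (adjusted p of 2.46e-05 to 0.0077, and 0.44 or more with an estimated correlation).

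**Figure D5:**
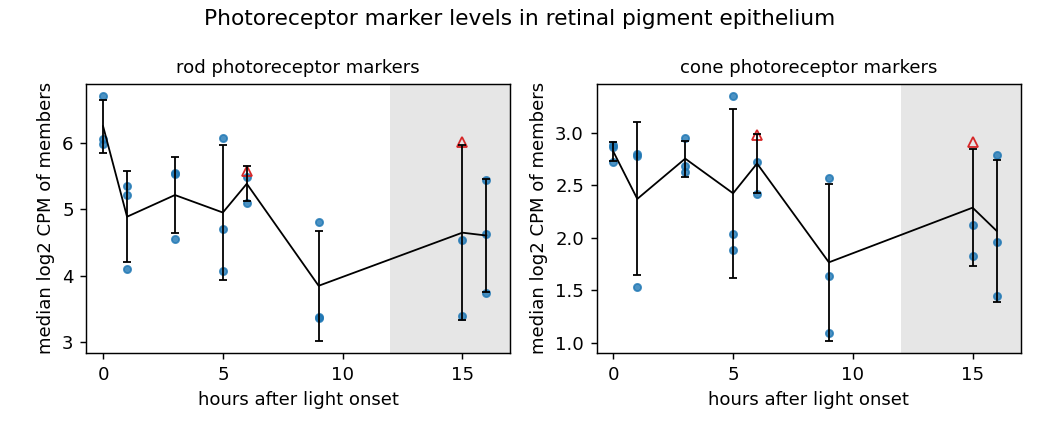
Median log2 CPM of rod and cone markers (y axis) against hours after light onset (x axis), with points for mice, open red triangles for mouse 3 of 6 h and mouse 3 of 15 h, and lines and bars for mean ± SD (n = 3). Rod markers go from 6.25 ± 0.40 at 0 h to 3.85 ± 0.83 at 9 h.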

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

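Results of named genes are compared first by their side of the threshold and then by direction. Of the named gene results, 469 kept their side of the threshold with DESeq2 and 137 gained a call, against 619 kept, 9 lost and 4 gained with limma-voom, 627, 4 and 1 with RLE factors, and 620, 7 and 5 with upper-quartile factors. Without a low-count filter 611 were kept, 20 lost and 1 gained, and with the stricter filter 600 were kept and 9 gained. Among the named genes and the union of lysosomal and autophagy genes with its 5 parts, 2 called values turned direction. The test over time has no direction to turn, and a 24 h component could turn only through a large move of its peak. The fitted peak of Col3a1 moved from 2.2 h to 18.9 h without 15 h and 16 h, with a log2 ratio of 0.58 (adjusted p = 0.124). The mean log2 change of lysosomal hydrolases at 15 h was -0.019 in the 22 libraries with the rod covariate. Except where construction is given as the reason, the cause was not tested. Depth was alike across libraries (14073440 to 17492470 counts).

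Values that moved are given in the order of genes varying over time, lysosomal and autophagy genes varying over time, genes with a 24 h component, lysosomal and autophagy genes with a 24 h component, then 1, 3, 5, 6, 9, 15 and 16 h against 0 h and night against day. The values from 24 libraries were 195, 1, 302, 0, 2, 0, 20, 30, 135, 74, 21 and 251. DESeq2 gave 1930, 12, 763, 4, 11, 5, 139, 174, 359, 1854, 130 and 651. On simulated data, drawn from edgeR dispersions and with no library standing apart, 16% to 20.3% of its calls were false. Its share of false calls in the real data is not known. The 22 libraries, chosen after seeing the data, gave 2882, 21, 1149, 13, 66, 55, 548, 423, 1497, 259, 405 and 843. The 22 libraries with the rod covariate, also chosen after, gave 2221, 13, 851, 6, 22, 23, 309, 321, 36 (15 h), 103 (16 h) and 719, with 9 h at 197 within 1.5 times. Library weights in limma-voom, chosen after, gave 8766, 93, 1651, 18, 2107, 360, 1608, 4320, 3482, 1606, 1569 and 1992.

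With the rod covariate 24 h genes numbered 883, lysosomal and autophagy genes among them 7, and calls 6 at 9 h, 3605 at 15 h, 13 at 16 h and 412 for night. Fits of the 2 groups alone gave 31, 11, 463, 4, 899, 0 and 170 from 1 h to 16 h. Without a filter, with more genes tested, lysosomal and autophagy genes over time numbered 0, and calls 1 at 3 h, 16 at 6 h, 61 at 9 h, 37 at 15 h and 143 for night. For lysosomal and autophagy genes, RLE factors gave 0 over time, and upper-quartile factors 1, the stricter filter 2 and the fit without 15 h and 16 h 2 with a 24 h component. Without 0 h, 135 genes had a 24 h component. Limma-voom moved only 15 h, to 49. With upper-quartile factors the split of higher and lower calls was 31 and 50 at 15 h (35 and 39 with TMM) and 117 and 111 for night (159 and 92). The 2 other definitions of day moved the night count by less than 1.5 times.

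Leaving out each library in turn gave, lowest and highest, 123 and 1226 genes over time, 0 and 5 lysosomal and autophagy genes over time, 209 and 806 genes with a 24 h component, 0 and 8 lysosomal and autophagy genes with one, 2 and 19 at 1 h, 0 and 4 at 3 h, 8 and 194 at 5 h, 8 and 588 at 6 h, 25 and 582 at 9 h, 2 and 3423 at 15 h, 7 and 148 at 16 h, and 122 and 1288 for night. These fits keep at least 2 libraries per time.

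Nothing in the labels says that a mouse number marks a shared litter, cage or day, and the data did not settle it. Of 84 pairs of libraries with the same number, 17 had deviations that correlated above 0.1 (range -0.32 to 0.53), and 14 of 24 libraries correlated best with their own number. Numbers shuffled within each time gave a mean of 8 (permutation p = 0.0517, a test added after seeing the data), and over the 22 libraries 11 did against 7.3 (permutation p = 0.156). A shared factor behind the numbers was thus neither shown nor excluded. With the number as a replicate block, lysosomal and autophagy genes numbered 0 over time and 1 with a 24 h component, and calls 1 at 3 h, 12 at 5 h and 87 at 9 h. Of the named gene results 613 kept their side of the threshold under the block, 14 lost and 5 gained a call, and all 48 list results kept theirs.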

Other observations

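The tests chosen only after the result was seen were those of gene length, depth, time of day and mitochondrial transcripts for the libraries that stood apart, of covariation for the rod markers, of Xist and of the ratios for the Y-linked genes, and all counts over other assignments of libraries. Immediate early genes, which respond within minutes to stimulation, had medians of -0.30, -0.41, 0.26 and -0.20 at 5, 6, 9 and 16 h against 0 h (camera adjusted p = 0.000768, 0.00602, 0.00125 and 0.0228, and adjusted p = 0.656, 0.723, 0.658 and 0.787 with an estimated correlation). Egr1 was the member that varied over time (adjusted p = 0.00819), and 7 of 23 did when adjusted over the list alone. Heat shock genes had a median of -0.13 at 9 h and 0.17 for night against day (0.00708 and 0.00019, and adjusted p = 0.558 and 0.368 with an estimated correlation). The night value took in a deviation of 0.23 in mouse 3 of 15 h, and was 0.09 in the 22 libraries (0.00521). Cholesterol synthesis genes had -0.18 for night against day (0.0179, and adjusted p = 0.658 with an estimated correlation), with -0.57 in mouse 3 of 15 h and -0.13 in the 22 libraries (0.000255). Melanin and pigment granule genes had -0.17 at 9 h (0.0111, and adjusted p = 0.584 with an estimated correlation). Endothelial markers had 0.49 at 9 h and -0.33 for night against day (5.78e-05 and 0.00149, and adjusted p = 0.629 and 0.705 with an estimated correlation). Camera calls of this list included 1 h too (higher, adjusted p = 0.00427), where 31 of 100 assignments of libraries gave a p as small. That call did not hold with an estimated correlation.

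Mouse 3 of 15 h and mouse 3 of 6 h were weighed first. Loss of long transcripts, a sign of RNA quality, fits as a candidate explanation, since the rho of deviation and gene length was -0.32 in mouse 3 of 15 h and -0.41 in mouse 3 of 6 h against -0.20 to 0.19 in the others. RNA of another cell type was set against it by comparing short with long red cell markers, which differed by 2.51 in log2, but the test could not have passed (exact permutation p = 0.4, smallest possible 0.2), so blood RNA stays open as a part, with the globin gene Hbb-bs at 4740 CPM against 538. So does RNA of other cells, since skeletal muscle markers deviated by 2.39 in mouse 3 of 15 h (-0.19 in mouse 3 of 6 h, -1.45 to 1.51 in the others), and macrophage and mast cell markers by 0.79 and 0.80 (others at most 0.43). As the whole cause in mouse 3 of 15 h, RNA of another cell type is argued against, because dilution would lower mitochondria-encoded and RPE genes alike, and the former were lower by -1.85 in log2 (-2.19 and -0.33, permutation p = 0.00397). That p permutes genes within 1 library, which are not independent replicates, so the argument rests on the sizes. In the other 22 libraries these lists deviated by -0.47 to 0.75 and by -0.23 to 0.21. Depth is argued against by a total of 15.2 M counts, and time of day by 0 of the 4 other mice of these times lying outside the range of the remaining libraries.

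Rod markers were highest at 0 h. Photoreceptor RNA carried along in differing amounts is a candidate explanation, since within a time the 20 rod markers varied together with a mean correlation of 0.80 against 0.04 for the 95th percentile of random lists. Time of day stays open (adjusted permutation p = 0.281, and 0.117 in the 22 libraries), and both may act. This doubt covers Pde6a, Nr2e3 and Rp1, which are rod markers themselves, and Impg1 and Fabp12. Within times Impg1 and Fabp12 followed the rod level over the 22 libraries (r = 0.94 and 0.79, 95th percentile of all genes 0.49, a test also chosen after). Their falls at 9 h shrank from -3.29 (SE 0.67) and -3.085 (SE 0.66) to -1.24 (SE 0.67) and -1.08 (SE 0.52) with the rod covariate. Lrtm1 is left open (r = 0.65), since its fall shrank less, from -3.12 (SE 0.65) to -2.22 (SE 0.85). Esrrb, Ptprn, Pitpnm3 and Casz1 are left open too. Their means were highest at 0 h (33, 13.8, 32.9 and 20.4 CPM), with fitted peaks at 22.5 h. Their correlation with the rod level within times was not computed.

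Y-linked genes were low in mouse 2 of 9 h, where Ddx3y was at 29.8 CPM against a mean of 106 ± 10.9 in the 21 other libraries that did not stand apart, Eif2s3y at 19 against 49.2 ± 5.45, Kdm5d at 9.42 against 27 ± 4.56 and Uty at 6.87 against 22.9 ± 3.29. In mouse 3 of 15 h and mouse 3 of 6 h, Kdm5d was at 6.94 and 16.2, Uty at 8.83 and 15.9, Ddx3y at 74.3 and 98.6 and Eif2s3y at 42.6 and 63.5. RNA of a female mouse is argued against by an Xist level of 0.47 CPM, within the 0 to 0.97 of the others, and RNA quality by a rho of -0.126, within the -0.20 to 0.19 of the 21. The 4 genes were lowered alike, with an SD of their log2 ratios of 0.16 (0.02 to 0.28 in the 21, 0.82 in mouse 3 of 15 h and 0.41 in mouse 3 of 6 h), which is consistent with fewer Y chromosomes in the sample, a hypothesis found and tested on the same data. No explanation from the study's groups was tested.

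Chance was set against each count by reassigning libraries to times. Chance is argued against, but not excluded, for genes varying over time (195, highest other 385, 2 of 100 assignments as large, the real one included). The same holds for genes with a 24 h component (302, highest other 5, 1 of 100) and for night against day (251, highest other 2134, 3 of 100). These shares were not adjusted for the number of counts weighed. The assignments with 385, 2134 and 662 calls held both libraries that stood apart in 1 group, which points to a structure of the samples. Placing both together was not enough, since 2 of 3 such assignments to times and 7 of 9 to night gave 0 calls. For the 76 list calls the assignments do not argue against chance (6 of 100, highest other 80). For counts of lysosomal and autophagy genes the assignments decide nothing. The count of 1 over time (highest other 2, 2 of 100) depends on a threshold set by all genes, and a count of 0 with a 24 h component is equalled by any assignment (100 of 100, highest other 0). For the camera p of the union and its 5 parts over 8 contrasts, 48 tests, 6 had a p as small in under 5 of 100 assignments, with no adjustment for their number. They were the union at 5 h (3) and 6 h (1), hydrolases at 6 h (1), membrane proteins at 5 h (1), and autophagy machinery (2) and selective receptors (1) at 16 h. For pairs of groups the 10 splits are too few, with real and highest other counts of 2 and 0 at 1 h, 0 and 0 at 3 h (10 splits as large), 20 and 0 at 5 h, 30 and 0 at 6 h, 135 and 1 at 9 h, 74 and 2 at 15 h and 21 and 0 at 16 h.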
